A study of Mus musculus with 16 samples.

How the data were processed

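RNA was measured in 16 mouse libraries from neural stem cell-derived OPCs in 4 groups of 4: WT-labelled and RXRgKO-labelled, untreated or with T3 for 24 h. Per the labels' protocols, cells were taken on day 4 of monolayer culture, and 200 ng of RNA went into poly-A selected, dUTP-stranded libraries. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, STAR 2.5.3a and HTSeq 0.6.1p1 with the mm10 build; the strand setting of the counting and the annotation release are not given in the sources used here. The deposited values are raw counts per Ensembl gene for 55335 genes, followed by 5 HTSeq summary lines that were left out of all gene tests. Symbols and positions came from GENCODE M21 on GRCm38, which held 55154 of the identifiers.

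Libraries held 18262279 to 42588442 gene counts, and 27566 to 41671 genes had a count. Of all reads the files account for, 22.4% to 46.7% lay in genes, 39.6% to 55.0% were placed at several sites and 11.5% to 23.5% lay in no annotated gene. Mitochondrially encoded genes took 1.06% to 1.86% of gene counts and the top 10 genes 7.63% to 15.4%. Counting error is covered by the count model, and reads without molecular identifiers are not independent molecules.

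Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. All 16 libraries entered 1 edgeR quasi-likelihood fit with a mean per group, robust dispersions, TMM factors and filterByExpr by group, which left 19764 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM are TMM-normalised, and log2 CPM used a prior count of 2. The T3 response difference is the T3 change under the RXRgKO label minus that under the WT label. Of 27 gene lists, 26 were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison, and sex-linked genes are given as values. The amplitude test was limma's fry on genes called when T3 was averaged over genotype labels, each signed by that average. Measures per library were compared by exact permutation tests, two-sided, in which 4 against 4 cannot give a p below 0.0286.

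Groups, comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took Rxrg, the 8 largest rises and 8 largest falls per comparison among called protein-coding genes with a mean of at least 2 CPM in the higher group and no overlap between libraries, up to 4 members of each list by smallest adjusted p, the 2 highest-expressed members of each list of another cell type, 10 genes for the response difference, up to 6 called Rxrg neighbours, and sex-linked genes. It gives 281 genes, of which the text names 132, a part chosen after their values were seen. Results for some genes are not reported here.

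Library pairs within a group were compared by a chi-square per gene over genes with summed counts from 20 to under 500, and libraries under a limit of 3 formed a set. Whether replicate numbers pair libraries across groups was checked from correlations of residuals. For T3 in the WT-labelled libraries the same-number correlations were 0.648, 0.247, 0.211 and 0.164, so numbers were taken as pairs there. However, only replicate 1 correlated best with its own number. For the others the pairing is not established, and Xist and Y-linked genes argue against the same cultures in both treatments. For T3 in the RXRgKO-labelled libraries they were 0.543, -0.629, -0.697 and 0.600, and they were mixed between genotype labels, so no pairing was used.

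Alternatives were DESeq2, limma voom, DESeq2 size factors within edgeR, no low-count filter (49786 genes), a filter of 1 CPM in 4 libraries, non-robust dispersions, only the groups compared, a replicate block, each library left out in turn, an estimated inter-gene correlation, fry, and 25 or 100 neighbours. Chosen after seeing the data were the library set as a term, counts summed per set, the share of reads outside genes as a covariate, leaving out WT-labelled replicate 1 or either RXRgKO-labelled set, a block on the WT-labelled libraries alone, and all omissions for gene lists.

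The pipeline was tested on simulated data in which 200 genes changed by 1.5, 2 or 4-fold. For T3 in the WT-labelled libraries it recovered 10.4%, 56.7% and 92.4% of them, for T3 in the RXRgKO-labelled libraries 14.9%, 58.2% and 97.0%, for the genotype labels without T3 13.4%, 56.7% and 97.0%, with T3 10.4%, 62.7% and 93.9%, and for the response difference 2.99%, 32.8% and 80.3%. False calls were 6 of 114, 7 of 121, 3 of 117, 4 of 117 and 1 of 80. A simulated set of 20 genes changed by 1.5-fold was called in each of the 5 comparisons and 0 of 25 random sets were. A true amplitude difference of -1 was returned as -0.948 and a true 0 as 0.0118. Genes and libraries were simulated independently, without library sets or correlation between genes. These rates therefore do not cover such structure in the real data.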

Results

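Per the labels' protocols, poly-A RNA was sequenced from mouse oligodendrocyte precursor cells (OPCs) grown from neural stem cells, on day 4 of monolayer culture. The labels give 4 groups of 4 libraries: wild type (WT) or RXRgKO, which the design text describes as lacking both copies of the gene for the retinoid X receptor gamma, each untreated or given the thyroid hormone triiodothyronine (T3) for 24 h. Each library held 18262279 to 42588442 counts in genes and 27566 to 41671 genes with at least 1 count, and 19764 genes passed the count filter. Nothing in the labels says that the 4 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries.

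Rxrg (ENSMUSG00000015843; GRCm38 chromosome 1, 167598384 to 167639623), the targeted gene, went against the genotype labels. Its normalised count was 1.51 ± 0.282 CPM (library-size normalised; SD, n = 4) in the untreated WT-labelled libraries and 4.25 ± 0.546 in the untreated RXRgKO-labelled libraries, and 0.703 ± 0.271 and 4.92 ± 0.493 after T3. The log2 fold change between genotype labels was 1.48 (SE 0.22, adjusted p = 2.0e-04) without T3 and 2.79 (SE 0.23, adjusted p = 8.8e-07) with T3, and every RXRgKO-labelled library lay above every WT-labelled library. With T3, Rxrg fell by 1.10 on the log2 scale (SE 0.24, adjusted p = 0.00908) in the WT-labelled libraries and had a value of 0.21 (SE 0.20, adjusted p = 0.64) in the RXRgKO-labelled ones. The labels do not say which part of the gene was disrupted, and counts per gene cannot show where in it the reads lie, so directions between genotypes are given below as between labels.

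**Figure D1:**
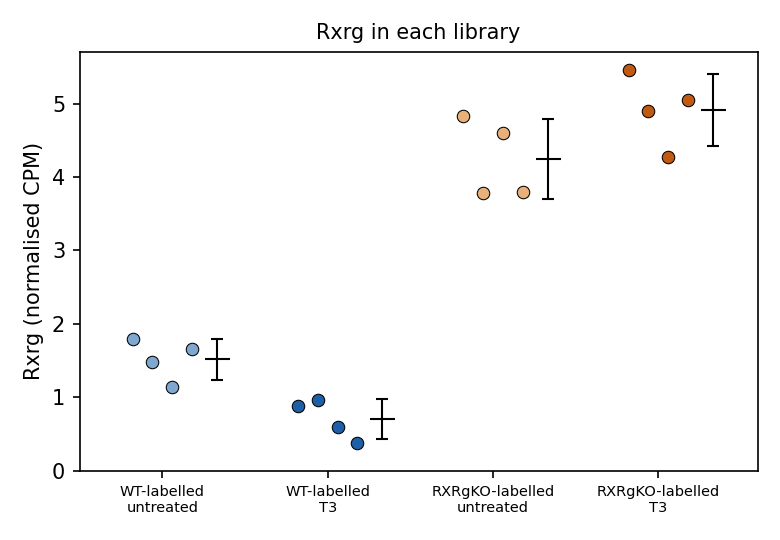
Rxrg in CPM (vertical axis) in each of the 16 libraries by genotype label and treatment; points are libraries and bars show the mean ± SD of 4. The 8 RXRgKO-labelled libraries lie above the 8 WT-labelled ones, with group means of 4.25 and 4.92 against 1.51 and 0.703 CPM.

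The libraries of each group fell into sets that resembled each other more closely than the rest. Within sets, the chi-square per gene between libraries was 1.503 to 2.12, and between sets of 1 group it was 4.94 to 9.62. Values within sets were above sampling noise, which repeat libraries of a single culture would exceed too, so they do not tell whether a set holds separate cultures; each library was entered as a replicate, as the labels number them. Replicate 1 stood alone in both WT-labelled groups, with Gfap, an astrocyte filament gene, at 4728 CPM untreated and 11207 with T3, against 819 to 1001 and 2455 to 2834 in the other libraries. Xist, transcribed from the inactive X chromosome of female cells, was at 1.39 to 3.75 CPM in untreated RXRgKO-labelled replicates 1 and 3 and T3-treated replicates 1 and 2, and at 276 to 1382 CPM in the other 12 libraries. Ddx3y, a Y-linked gene, was above 13 CPM in every library. In WT-labelled replicates 2 to 4, Ddx3y was at 13.9 to 15.8 CPM untreated and 68.1 to 78.3 CPM with T3. Xist in these libraries was at 1198 to 1382 and 276 to 365 CPM. Of the 5 sex-linked genes, Xist was lower with T3 in replicates 2 to 4 and the 4 Y-linked ones were higher. The median T3 change of the 5 was 2.31 on the log2 scale there and -0.21 in replicate 1. In replicate 1, Ddx3y was at 73.3 CPM untreated and 60.6 CPM with T3, and Xist at 526 and 401 CPM. For replicates 2 to 4 these values argue against the same cultures in both treatments. T3 changes in the WT-labelled libraries, given below, include that difference between treatments. The sets also differed in measures of the libraries. Rn7sk, an RNA without a poly-A tail, was at 17439 CPM untreated and 13321 CPM with T3 in WT-labelled replicate 1, against 66031 to 79523 and 43335 to 57854 CPM in replicates 2 to 4. Such counts go against libraries of poly-A RNA alone, which the labels' protocols describe. Gm10800, a predicted gene, was at 12655 to 22058 CPM in the RXRgKO-labelled libraries lacking Xist and 896 to 3374 CPM in those with Xist. Reads outside annotated genes made up 21.6% and 23.5% of the untreated and 16.8% and 18.7% of the T3-treated libraries lacking Xist, against 18.1% and 20.5% and 11.5% and 12.5% of those with Xist.

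The RXRgKO-labelled sets were matched between treatments by Xist alone, and in those with Xist, Ddx3y was at 51.2 and 52.9 CPM untreated and 20.7 and 22.1 CPM with T3. Of the 5 sex-linked genes, only 1, Xist, was higher with T3 there, and the median of the 5 was -1.28 on the log2 scale. In the set lacking Xist that median was 0.097, and Ddx3y was at 115 and 118 CPM untreated and 124 and 126 CPM with T3. For the set with Xist these values argue against the same cultures in both treatments. The set lacking Xist had no such difference, but it is not shown to be the same cultures either. T3 changes in the RXRgKO-labelled libraries and within the set with Xist, given below, include that difference.

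The first comparison asks which genes T3 changed in the WT-labelled libraries. Among the genes that rose most, on the log2 scale, were Clca3a1 (7.45, SE 0.37, adjusted p = 5.7e-09), a chloride channel accessory protein gene that went from 0.658 ± 0.287 to 117 ± 38.0 CPM (SD, n = 4), Rpe65 (5.33, SE 0.38, adjusted p = 3.7e-07), a retinoid isomerase gene, and Prph (5.50, SE 0.43, adjusted p = 8.7e-07), which encodes the filament peripherin. Next came Lpo (5.30, SE 0.51, adjusted p = 7.0e-06), lactoperoxidase, Col20a1 (5.19, SE 0.40, adjusted p = 8.6e-07), a collagen gene, Bcl3 (4.97, SE 0.41, adjusted p = 1.4e-06), a regulator of NF-kappaB, Trh (4.32, SE 0.65, adjusted p = 4.5e-04), thyrotropin-releasing hormone, and Gbp3 (4.08, SE 0.28, adjusted p = 2.6e-07). Among those that fell most were Angptl4 (-2.58, SE 0.57), an inhibitor of lipoprotein lipase, Fam129a (-2.15, SE 0.17) and Snhg11 (-1.96, SE 0.50). Further falls were Rph3a (-1.93, SE 0.26), Gucy2f (-1.90, SE 0.39), Eomes (-1.82, SE 0.40) and Arl4d (-1.81, SE 0.28), with adjusted p from 1.1e-06 to 0.0214.

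T3 response genes of neural cells rose, with 7 of 16 members higher, 0 lower and 9 not called (camera adjusted p = 3.8e-06). T3 response members adjusted over the list alone came to 9 higher and 0 lower, and the list had adjusted p = 0.0472 with an estimated correlation. Dio3, the deiodinase that inactivates T3, went from 0.190 ± 0.0888 to 1.98 ± 0.206 CPM, Hr, a nuclear receptor corepressor, from 36.9 ± 16.5 to 210.1 ± 55.2 CPM, and Stat5a (2.38, SE 0.32) and Dbp (1.28, SE 0.16) rose as well. Myelin and mature oligodendrocyte genes had 14 of 27 members higher, 0 lower and 13 not called (camera adjusted p = 6.6e-12). Myelin members adjusted over the list alone came to 17 higher and 0 lower, and the list had adjusted p = 0.0472 with an estimated correlation. Myelin examples were the myelin protein genes Opalin (3.41, SE 0.34) and Mog (3.02, SE 0.34), the transferrin gene Trf (2.12, SE 0.28) and Hapln2 (1.499, SE 0.24). Within library sets, the median T3 change of the myelin list was 0.51 for replicate 1 and 1.10 for replicates 2 to 4. For replicates 2 to 4, Xist and the Y-linked genes argue against the same cultures in both treatments. Genes of cholesterol synthesis and uptake had 8 of 25 members higher, 0 lower and 17 not called (camera adjusted p = 6.6e-12). Cholesterol members adjusted over the list alone came to 16 higher and 0 lower, and the list had adjusted p = 0.258 with an estimated correlation. Cholesterol examples were the synthesis enzymes Hsd17b7 (1.79, SE 0.14), Ebp (1.04, SE 0.12), Pmvk (0.74, SE 0.17) and Acat2 (0.72, SE 0.16).

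OPC markers had 0 of 21 members higher, 6 lower and 15 not called (camera adjusted p = 7.4e-04). OPC marker members adjusted over the list alone came to 0 higher and 8 lower, and the list had adjusted p = 0.551 with an estimated correlation. OPC marker falls included Tmem100 (-1.42, SE 0.11), Hes5 (-0.78, SE 0.20), a Notch target, Id4 (-0.69, SE 0.17) and the growth factor receptor gene Egfr (-0.67, SE 0.14). Neuron markers had 0 of 18 members higher, 5 lower and 13 not called (camera adjusted p = 0.00454). Neuron marker members adjusted over the list alone came to 0 higher and 7 lower, and the list had adjusted p = 0.73 with an estimated correlation. The interneuron transcription factors Dlx1 (-1.44, SE 0.26) and Dlx2 (-1.27, SE 0.25) and the GABA synthesis enzymes Gad1 (-1.42, SE 0.30) and Gad2 (-1.57, SE 0.35) fell, and WT-labelled replicate 1 was the lowest untreated library for this list, at a mean log2 CPM of 4.02 against 4.99 to 5.06. Immediate early genes had 4 of 13 members higher, 0 lower and 9 not called (camera adjusted p = 0.00158). Immediate early members adjusted over the list alone came to 6 higher and 1 lower, and the list had adjusted p = 0.146 with an estimated correlation. Immediate early rises included Fos (1.93, SE 0.27), Junb (1.55, SE 0.37) and Arc (1.51, SE 0.28). Hypoxia and glycolysis genes had 3 of 18 members higher, 0 lower and 15 not called (camera adjusted p = 0.00384). Hypoxia members adjusted over the list alone came to 4 higher and 0 lower, and the list had adjusted p = 0.551 with an estimated correlation. Hypoxia examples were the oxygen sensor Egln3 (1.26, SE 0.15) and the phosphofructokinase Pfkp (0.85, SE 0.20). Members of lists that were not called as a whole also changed: the axon guidance genes Slit1 (-1.77, SE 0.22) and Sema3c (2.04, SE 0.39), the matrix gene Tnc (-1.45, SE 0.34), the peroxisomal enzyme Ehhadh (1.40, SE 0.25), the filament gene Vim (1.00, SE 0.16), and Kif19a (2.167, SE 0.45) and Rras2 (1.00, SE 0.20) of the premyelinating list. For replicate 1 and for replicates 2 to 4, the median T3 changes were 0.34 and 0.72 for the cholesterol, -0.23 and -0.42 for the OPC, -0.10 and -0.65 for the neuron and 0.14 and 0.47 for the hypoxia list.

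Gfap had a value of 1.37 (SE 0.68, adjusted p = 0.251) for T3 in the WT-labelled libraries, with replicate 1 far above the others in both treatments. It was higher with T3 for each of the 4 replicate numbers. Only replicate 1 correlated best with its own number, and for replicates 2 to 4 Xist and Y-linked genes argue against pairs of the same cultures. The value was 1.48 (adjusted p = 4.9e-06) with the replicate block on the WT-labelled libraries alone, 1.49 (adjusted p = 1.1e-05) with the library set as a term and 1.46 (adjusted p = 0.0646) with the block in all 16 libraries. It was 2.45 (adjusted p = 0.0200) without untreated replicate 1, 0.48 (adjusted p = 0.692) without T3-treated replicate 1 and 1.29 (adjusted p = 1) with counts summed per set, so whether Gfap passed depended on these settings.

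In all, 1668 genes passed edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05, 980 higher and 688 lower with T3, and 761 of them changed at least 2-fold. Beside them, the share of reads outside annotated genes was 17.1% ± 0.483 untreated and 13.5% ± 0.940 with T3 (SD, n = 4; exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give, and 0.305 after adjustment). Replicate numbers of the WT-labelled libraries were taken as pairs from correlations of residuals, although only replicate 1 correlated best with its own number and Xist and Ddx3y differed between treatments in replicates 2 to 4. A fit with that block on these 8 libraries called 5084 genes, a fit with the library set as a term 7599, and counts summed per library set 15. With the share of reads outside genes as a covariate, which in these libraries does not overlap between treatments, it was 4744 (2190 higher and 2554 lower), so the larger direction turned. The count was 997, 998 and 1009 without untreated replicate 2, 3 or 4, and 1065 without T3-treated replicate 4.

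The second comparison asks the same of T3 in the RXRgKO-labelled libraries. The genes that rose most, on the log2 scale, were Clca3a1 (7.01, SE 0.37, adjusted p = 2.3e-08), Opalin (5.49, SE 0.38, adjusted p = 4.5e-07), Prph (4.93, SE 0.34, adjusted p = 4.1e-07), and Col20a1 (4.23, SE 0.39, adjusted p = 9.0e-06). The next were Lpo (4.17, SE 0.47, adjusted p = 5.5e-05), Dio3 (4.00, SE 0.37, adjusted p = 9.0e-06), Bcl3 (3.76, SE 0.37, adjusted p = 1.7e-05) and Mog (3.68, SE 0.38, adjusted p = 2.3e-05). Opalin went from 0.830 ± 0.0832 to 37.6 ± 10.5 CPM (SD, n = 4). Those that fell most were the transcription factor genes Ebf2 (-1.68, SE 0.26), Irx1 (-1.38, SE 0.25) and Lhx6 (-1.24, SE 0.21), and the calcium-binding copine Cpne6 (-1.503, SE 0.22). The next 4 were Hspa12b (-1.29, SE 0.30), Tmem100 (-1.17, SE 0.11), the glutamate receptor subunit Grin3a (-1.15, SE 0.24) and the melanocortin receptor Mc5r (-1.12, SE 0.22), with adjusted p from 1.2e-05 to 0.0287.

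T3 response genes of neural cells had 6 of 16 members higher, 0 lower and 10 not called (camera adjusted p = 2.3e-06). T3 response members adjusted over the list alone came to 6 higher and 0 lower, and the list had adjusted p = 0.0417 with an estimated correlation. T3 response rises included Hr (3.21, SE 0.32), Klf9 (2.25, SE 0.30), a transcription factor gene bound by T3 receptors, and Dbp (1.85, SE 0.16), a clock output factor. Myelin and mature oligodendrocyte genes had 10 of 27 members higher, 0 lower and 17 not called (camera adjusted p = 4.0e-13). Myelin members adjusted over the list alone came to 15 higher and 0 lower, and the list had adjusted p = 0.0372 with an estimated correlation. Myelin examples were Cldn11 (2.94, SE 0.26), the myelin tight junction gene, and Ugt8a (1.52, SE 0.18), the galactolipid synthase. The median T3 change of the myelin list was 1.01 in the libraries with Xist and 0.42 in those lacking it. Committed and premyelinating oligodendrocyte genes had 4 of 17 members higher, 0 lower and 13 not called (camera adjusted p = 0.00317). Premyelinating members adjusted over the list alone came to 4 higher and 0 lower, and the list had adjusted p = 0.599 with an estimated correlation. Premyelinating examples were Tmem163 (2.98, SE 0.45), Kif19a (2.86, SE 0.48), Cnksr3 (1.68, SE 0.34) and Rras2 (0.91, SE 0.20). Cholesterol genes had 2 of 25 members higher, 0 lower and 23 not called (camera adjusted p = 5.6e-05). Cholesterol members adjusted over the list alone came to 2 higher and 0 lower, and the list had adjusted p = 0.592 with an estimated correlation. Cholesterol examples were Ebp (0.71, SE 0.12) and Hsd17b7 (0.53, SE 0.13).

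Cell cycle genes had 0 of 30 members higher, 1 lower and 29 not called (camera adjusted p = 4.8e-08). Cell cycle members adjusted over the list alone came to 0 higher and 1 lower, and the list had adjusted p = 0.592 with an estimated correlation. The kinetochore gene Cenpf (-0.85, SE 0.15) fell, and the proliferation marker Mki67 had a value of -0.71 (SE 0.21, adjusted p = 0.0889). The list's median was -0.89 in the libraries with Xist and -0.24 in those lacking it. OPC markers had 0 of 21 members higher, 2 lower and 19 not called (camera adjusted p = 0.0235). OPC marker members adjusted over the list alone came to 0 higher and 2 lower, and the list had adjusted p = 0.599 with an estimated correlation. OPC marker falls included Tmem100 and Egfr (-0.68, SE 0.14). Immediate early genes had 2 of 13 members higher, 0 lower and 11 not called (camera adjusted p = 6.6e-04). Immediate early members adjusted over the list alone came to 5 higher and 0 lower, and the list had adjusted p = 0.106 with an estimated correlation. Immediate early examples were Fos (1.45, SE 0.27) and Junb (1.44, SE 0.36). Hypoxia and glycolysis genes had 1 of 18 members higher, 0 lower and 17 not called (camera adjusted p = 0.00681). Hypoxia members adjusted over the list alone came to 4 higher and 0 lower, and the list had adjusted p = 0.592 with an estimated correlation. The called hypoxia member was Egln3 (0.73, SE 0.15). Microglia and macrophage markers had a median of -0.60 and 0 of 13 members higher, 0 lower and 13 not called (camera adjusted p = 0.0405). Microglia members adjusted over the list alone came to 1 higher and 0 lower, and the list had adjusted p = 0.599 with an estimated correlation. In the libraries with Xist and in those lacking it, the median T3 changes were -1.54 and -0.11 for the microglia, 0.47 and 0.20 for the premyelinating, 0.16 and 0.46 for the cholesterol and -0.11 and -0.29 for the OPC list. They were 0.73 and 0.25 for the immediate early and 0.34 and 0.18 for the hypoxia list. By camera, OPC markers were not called without untreated replicate 2 or 4 or T3-treated replicate 1 or 2 (adjusted p = 0.0842 to 0.229), nor microglia markers without untreated replicate 1 or 3 or T3-treated replicate 3 or 4 (0.0942 to 0.39). Without T3-treated replicate 1 the microglia median was -1.29. Cholesterol genes (0.188) and OPC markers (0.154) were not called without the libraries lacking Xist, nor microglia markers without those with Xist (0.816). Outside the called lists, the neurofilament Nefl (1.01, SE 0.15), the guidance gene Sema3d (1.39, SE 0.25) and the transglutaminase Tgm2 (1.58, SE 0.23) rose.

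The test called 555 genes, 398 higher and 157 lower, 279 of them by at least 2-fold. Beside them, the share of reads outside annotated genes was 20.9% ± 2.29 untreated and 14.9% ± 3.41 with T3 (SD, n = 4; exact permutation test, two-sided, p = 0.0571, 0.406 after adjustment). The count was 4989 (2180 higher and 2809 lower) with that share as a covariate, so the larger direction turned, 6634 with the library set as a term, 129 without the 4 libraries that had Xist, 3 with counts summed per set, and 1194 by DESeq2. It was 359, 275 and 253 without untreated replicate 1, 2 or 4, and 322 and 294 without T3-treated replicate 3 or 4.

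The T3 responses under the 2 genotype labels were then set against each other. Of the genes called, 317 rose and 67 fell under both labels, where independent lists would share 19.7 and 5.47, and 0 changed in opposite directions by this test. Clca3a1, Prph, Col20a1, Lpo, Bcl3 and Dio3 are among the shared rises and Tmem100 and Egfr among the shared falls. Across the 19764 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.670 and Spearman's rho = 0.672. With counts summed per set the overlap was 2, and it was 4117 with the set as a term and 121 without the RXRgKO-labelled libraries with Xist. Without RXRgKO-labelled untreated replicate 1, 2 or 4 it was 255, 217 and 200, and without T3-treated replicate 3 or 4 it was 242 and 240.

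**Figure D2:**
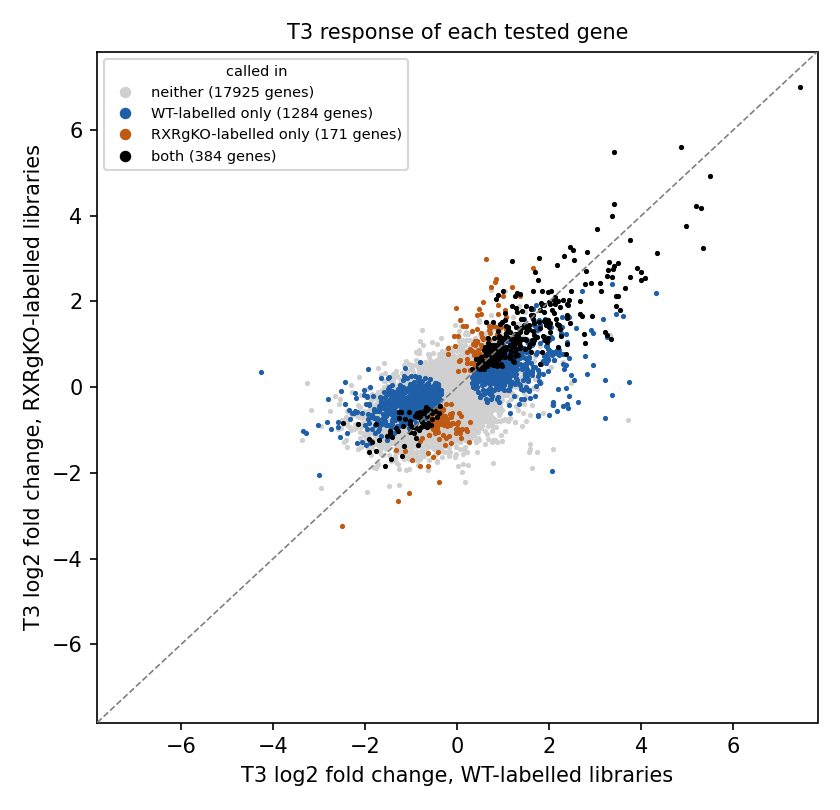
T3 log2 fold change of each of the 19764 tested genes in the WT-labelled (horizontal axis) and RXRgKO-labelled libraries (vertical axis); colours mark genes called under either label or both, and the dashed line marks equal responses. The 384 genes called under both labels lie in the upper right and lower left, and a call under a single label does not show that the responses differ.

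The difference of the T3 response between labels was tested gene by gene. The test called 13 genes, 2 with a higher and 11 with a lower signed T3 change in the RXRgKO-labelled libraries. Hsd17b7, a cholesterol synthesis enzyme gene near Rxrg on chromosome 1, changed by 1.79 in the WT-labelled and 0.53 in the RXRgKO-labelled libraries, a difference of -1.27, SE 0.19, adjusted p = 0.0143. The procollagen enhancer Pcolce (difference -2.04, SE 0.31, adjusted p = 0.0182), the matrix gene Thbs2 (difference -1.59, SE 0.20, adjusted p = 0.00601), the protease Ctsc (difference -1.24, SE 0.19, adjusted p = 0.0182) and the phosphate transporter Slc20a2 (difference -1.08, SE 0.18, adjusted p = 0.0327) rose with T3 in the WT-labelled libraries by 3.26, 2.35, 1.62 and 1.20, and had values of 1.22, 0.77, 0.38 and 0.12 in the RXRgKO-labelled ones, where Ctsc and Slc20a2 did not pass. Arhgap28 (difference -1.75, SE 0.29, adjusted p = 0.0327) and Prr5l (difference -1.13, SE 0.18, adjusted p = 0.0182) rose by 1.35 and 0.85 in the WT-labelled libraries and had values below 0, -0.40 and -0.28, that did not pass in the RXRgKO-labelled ones. Edil3 had values of -0.21 in the WT-labelled and 0.90 in the RXRgKO-labelled libraries, and Fam135b had values of -1.65 and 0.21. Their differences were 1.11 (SE 0.14) and 1.86 (SE 0.24), both at adjusted p = 0.00601. Rxrg itself had a difference of 1.31 (SE 0.32, adjusted p = 0.214).

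Cell cycle (median -0.33), cholesterol (-0.30) and mesenchymal and mural genes (-0.58) had lower signed T3 changes in the RXRgKO-labelled libraries, and neuron markers (0.56) and extracellular matrix and axon guidance genes (0.46) higher ones, at adjusted p = 4.4e-05, 7.1e-07, 0.00264, 4.4e-05 and 0.0282. A lower signed change is not always a weaker one: under the WT and RXRgKO labels, the median T3 change was -0.13 and -0.43 for the cell cycle, 0.59 and 0.32 for the cholesterol, 0.25 and -0.32 for the mesenchymal, -0.60 and -0.03 for the neuron and -0.17 and 0.04 for the matrix list. With an estimated correlation, none of these 5 passed, at adjusted p = 0.91, 0.886, 0.13, 0.886 and 0.91. With the preset correlation, 4 of them kept their call with the replicate block and 3 with counts summed per set. Without the RXRgKO-labelled libraries with Xist, the cell cycle, mesenchymal and matrix lists were not called (adjusted p = 0.358, 0.335 and 0.121). The matrix list was not called either without untreated WT-labelled replicate 3, T3-treated WT-labelled replicate 3 or 4, untreated RXRgKO-labelled replicate 1 or 3 or T3-treated RXRgKO-labelled replicate 3 or 4 (0.051 to 0.596). The cell cycle median was -0.21 and -0.23 without T3-treated RXRgKO-labelled replicate 3 or 4, and without untreated WT-labelled replicate 1 the cholesterol and neuron medians were -0.49 and 0.86. Of the members of these 5 lists, Hsd17b7 was the single gene called. Over the 3143 genes changed by T3 when both labels were averaged, the T3 response had a median of 0.714 in the WT-labelled and 0.532 in the RXRgKO-labelled libraries on the log2 scale. It was smaller in the latter for 69.4% of genes, with a median signed difference of -0.155 (fry p = 0.026, n = 16 libraries).

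The gene count was 4 with the replicate block, 1321 with the library set as a term, 0 with counts summed per set, 112 by DESeq2 and 118 without both WT-labelled libraries numbered 1. Without untreated WT-labelled replicates 1 to 4 in turn it was 40, 3, 7 and 3, and without the T3-treated ones 49, 7, 7 and 5. Without untreated RXRgKO-labelled replicates 2, 3 and 4 it was 4, 8 and 3, and without T3-treated replicates 1, 3 and 4 it was 6, 4 and 4. The signed difference was -0.0589 with the library set as a term (fry p = 0.0972, n = 16 libraries) and -0.429 with counts summed per set, and passed with neither. It was 0.0182 without the RXRgKO-labelled libraries lacking Xist, -0.257 without those with Xist, -0.238 without a low-count filter, and 0.161 with the share of reads outside genes as a covariate. It did not pass without RXRgKO-labelled untreated replicate 1 (-0.138) or T3-treated replicate 1 (-0.148) or 2 (-0.1005).

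The fourth comparison sets untreated RXRgKO-labelled against untreated WT-labelled libraries. Myelin genes were far lower in the RXRgKO-labelled libraries: Mbp, myelin basic protein, was at 193 ± 45.8 against 5174 ± 963 CPM (SD, n = 4; log2 fold change -4.74, SE 0.32, adjusted p = 1.0e-07). Of the genes that fell most, Mobp, a myelin protein gene, Tmem125, Ddc, Dct, Casr, the calcium-sensing receptor, and S1pr5, a sphingosine phosphate receptor of oligodendrocytes, had log2 fold changes of -7.01 (SE 0.65), -4.87 (SE 0.46), -4.69 (SE 0.40), -4.63 (SE 0.69), -4.57 (SE 0.34) and -4.46 (SE 0.37). Those that rose most were macrophage and microglia genes, Cd209f (6.42, SE 0.89, adjusted p = 1.2e-04), Fcrls (5.44, SE 0.58, adjusted p = 1.0e-05) and Ms4a6d (5.15, SE 0.68, adjusted p = 6.8e-05). These were followed by lysozyme Lyz2 (5.06, SE 1.11, adjusted p = 0.0056), the complement gene C1qc (4.90, SE 0.71, adjusted p = 1.9e-04), Adgre1 (4.52, SE 0.58, adjusted p = 5.4e-05) and Ms4a7 (4.40, SE 0.83, adjusted p = 0.00177), together with Ccn5 (4.36, SE 0.37, adjusted p = 9.4e-07), a matrix-associated protein gene. The direction of all of these is between labels that Rxrg went against.

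Myelin and mature oligodendrocyte genes had a median of -2.03 and 1 of 27 members higher, 20 lower and 6 not called (camera adjusted p = 1.2e-22). Myelin members adjusted over the list alone came to 1 higher and 23 lower, and the list had adjusted p = 0.002 with an estimated correlation. Mag, Cldn11 and Hapln2 among the falls had log2 fold changes of -3.73 (SE 0.25), -3.76 (SE 0.27) and -4.40 (SE 0.30). Committed and premyelinating oligodendrocyte genes had 0 of 17 members higher, 6 lower and 11 not called (camera adjusted p = 6.9e-04). Premyelinating members adjusted over the list alone came to 1 higher and 9 lower, and the list had adjusted p = 0.64 with an estimated correlation. Premyelinating examples were Tmem163 (-4.10, SE 0.47), Cnksr3 (-2.27, SE 0.35) and Rras2 (-1.32, SE 0.20). OPC markers had 0 of 21 members higher, 1 lower and 20 not called (camera adjusted p = 0.199). OPC marker members adjusted over the list alone came to 0 higher and 0 lower, and the list had adjusted p = 0.837 with an estimated correlation.

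Markers of some other cell types were higher beside these genes, while those of astrocytes (median -0.12, adjusted p = 0.83), neural stem cells (0.15, 0.111) and Schwann and neural crest cells (0.19, mean -0.41, 0.832) were not called. Mesenchymal and mural markers had 11 of 13 members higher, 0 lower and 2 not called (camera adjusted p = 1.0e-12). Mesenchymal members adjusted over the list alone came to 11 higher and 1 lower, and the list had adjusted p = 2.6e-04 with an estimated correlation. Mesenchymal examples were Acta2 (4.13, SE 0.47), smooth muscle actin, at 216 ± 120.0 against 12.4 ± 6.29 CPM, Tagln (3.51, SE 0.45), Col1a1 (3.33, SE 0.30) and Postn (2.69, SE 0.24). Endothelial markers had 4 of 7 members higher, 0 lower and 3 not called (camera adjusted p = 7.2e-05). Endothelial members adjusted over the list alone came to 4 higher and 0 lower, and the list had adjusted p = 0.0125 with an estimated correlation. Endothelial examples were Kdr (2.42, SE 0.31) and Cdh5 (2.42, SE 0.48). Microglia and macrophage markers had 12 of 13 members higher, 0 lower and 1 not called (camera adjusted p = 9.3e-12). Microglia members adjusted over the list alone came to 12 higher and 0 lower, and the list had adjusted p = 0.0807 with an estimated correlation. The complement gene C1qb was at 5.24 ± 1.87 against 0.454 ± 0.0823 CPM. Ependymal and ciliated markers had 6 of 7 members higher, 0 lower and 1 not called (camera adjusted p = 5.5e-08). Ependymal members adjusted over the list alone came to 7 higher and 0 lower, and the list had adjusted p = 0.0807 with an estimated correlation. Ependymal examples were Foxj1 (1.62, SE 0.18), a regulator of motile cilia, Cfap126 (2.42, SE 0.32) and Pifo (2.77, SE 0.50). In untreated RXRgKO-labelled libraries the mean log2 CPM of the ependymal list was 1.91 ± 0.628, and the libraries lacking Xist lay above those with Xist.

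**Figure D3:**
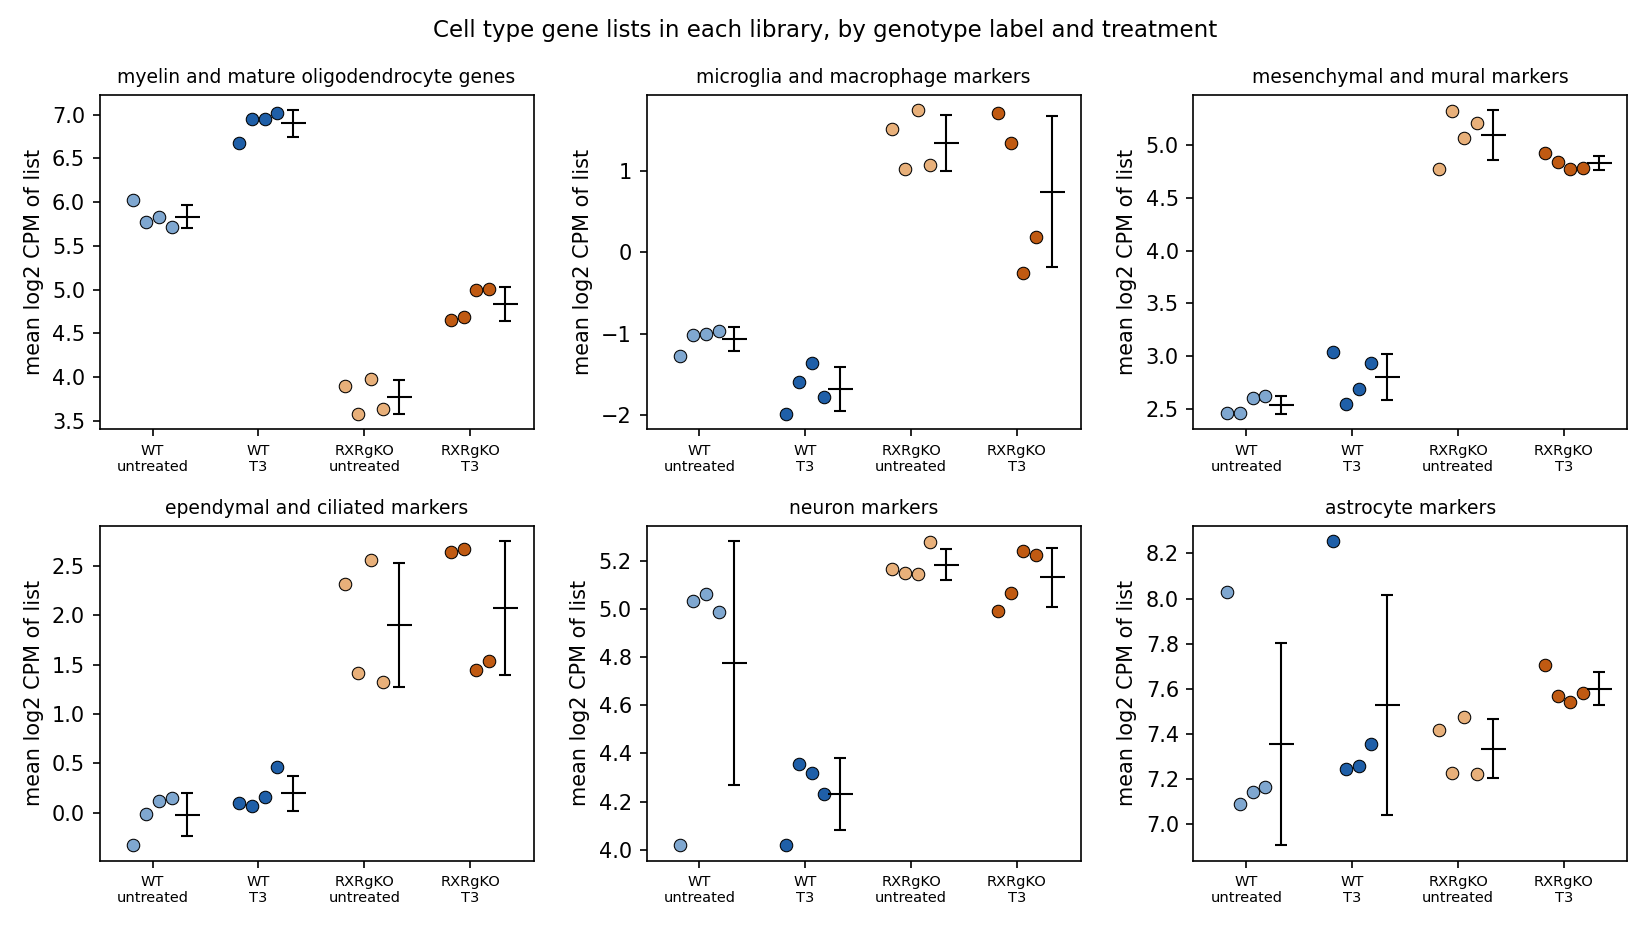
Mean log2 CPM of 6 gene lists (vertical axes) in each library by genotype label and treatment (horizontal axes); points are libraries and bars show the mean ± SD of 4. The myelin list averages 5.83 and 6.90 in the WT-labelled and 3.77 and 4.84 in the RXRgKO-labelled libraries, untreated and with T3, and the mesenchymal list 2.54 and 2.80 against 5.10 and 4.83.

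Interferon response genes had 7 of 15 members higher, 0 lower and 8 not called (camera adjusted p = 1.0e-06). Interferon members adjusted over the list alone came to 11 higher and 0 lower, and the list had adjusted p = 0.126 with an estimated correlation. Interferon examples were Usp18 (2.19, SE 0.38) and Ifitm3 (2.11, SE 0.36). Neuron markers had 2 of 18 members higher, 1 lower and 15 not called (camera adjusted p = 0.0192). Neuron marker members adjusted over the list alone came to 7 higher and 2 lower, and the list had adjusted p = 0.661 with an estimated correlation. Gad1 (1.11, SE 0.29) and Gad2 (1.37, SE 0.33) were higher and Elavl3 (-1.59, SE 0.33), an RNA-binding protein gene, lower. The mean log2 CPM of the neuron list was 5.14 to 5.28 in the RXRgKO-labelled libraries, 4.99 to 5.06 in WT-labelled replicates 2 to 4 and 4.02 in replicate 1, and without replicate 1 the median was 0.22 and the list was not called (adjusted p = 0.162); nor was it without RXRgKO-labelled replicate 4 (0.066). Cell cycle genes had 0 of 30 members higher, 3 lower and 27 not called (camera adjusted p = 5.7e-04). Cell cycle members adjusted over the list alone came to 0 higher and 4 lower, and the list had adjusted p = 0.661 with an estimated correlation. Cell cycle examples were Ube2c (-0.83, SE 0.20) and Cdc20 (-0.76, SE 0.18). Circadian clock genes had 0 of 16 members higher, 3 lower and 13 not called (camera adjusted p = 0.0108). Circadian members adjusted over the list alone came to 0 higher and 3 lower, and the list had adjusted p = 0.543 with an estimated correlation. Circadian examples were Bhlhe41 (-1.79, SE 0.18) and Nr1d1 (-0.60, SE 0.12). Mitochondrially encoded genes had 0 of 7 members higher, 0 lower and 7 not called (camera adjusted p = 0.00834). Mitochondrial members adjusted over the list alone came to 0 higher and 0 lower, and the list had adjusted p = 0.543 with an estimated correlation. The premyelinating, circadian and mitochondrial lists were not called without WT-labelled replicate 1 either (adjusted p = 0.0861, 0.0686 and 0.0686), and their medians were -0.39, -0.09 and -0.19. Without the RXRgKO-labelled libraries with Xist, the neuron, cell cycle and mitochondrial lists were not called (0.322, 0.0631 and 0.085), and without those lacking Xist the circadian list was not (0.0698). The T3 response list was not called (adjusted p = 0.813), but its members Hr (-1.46, SE 0.30), Klf9 (-1.15, SE 0.29) and Dbp (-0.78, SE 0.16) were lower. Other members went the other way, since the list's mean log2 CPM was 2.78 in the RXRgKO-labelled and 2.70 in the WT-labelled libraries. In WT-labelled replicate 1, Hr and Klf9 were at 61.5 and 50.4 CPM, against 26.8 to 29.6 and 19.3 to 23.5 CPM in replicates 2 to 4. The T3-producing deiodinase Dio2 (-1.20, SE 0.21) and the T3 receptor Thrb (-0.65, SE 0.13) were lower, while the cytosolic T3-binding protein Crym (3.50, SE 0.32) was higher. The guidance genes Sema4d (-2.21, SE 0.24) and Ephb1 (-2.27, SE 0.29) were lower and Vim (0.68, SE 0.16) was higher.

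The test called 2240 genes, 1220 higher and 1020 lower in the RXRgKO-labelled libraries, 1360 of them by at least 2-fold. Reads outside annotated genes made up 20.9% ± 2.29 of these libraries against 17.1% ± 0.483 (SD, n = 4; exact permutation test, two-sided, p = 0.0286, 0.305 after adjustment). The count was 4518 (1898 higher and 2620 lower) without the RXRgKO-labelled libraries with Xist and 141 (70 higher and 71 lower) with counts summed per set, so the larger direction turned in both. Each library set holds a single genotype label, so no value within a set can be given for this comparison. A set term cannot adjust it either: it takes the spread between sets out of the error, and the 8938 genes called with it are no adjusted estimate.

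The last comparison sets T3-treated RXRgKO-labelled against T3-treated WT-labelled libraries. Tmem125, at 0.491 ± 0.270 against 42.0 ± 14.8 CPM (SD, n = 4), was among the genes that fell most on the log2 scale (-6.52, SE 0.48, adjusted p = 2.5e-07), with the tight junction gene Cldn14 (-6.31, SE 0.50), Casr (-6.22, SE 0.34), Dct (-5.95, SE 0.69), Mobp (-5.87, SE 0.60), S1pr5 (-5.66, SE 0.37) and Ermn (-5.55, SE 0.61), a myelin cytoskeletal gene. The genes that rose most included macrophage and microglia genes, C1qc (5.45, SE 0.82, adjusted p = 2.2e-04), Lyz2 (5.39, SE 1.18, adjusted p = 0.00454) and the acute phase gene Saa3 (5.27, SE 1.24, adjusted p = 0.0074). Next were Fcrls (4.94, SE 0.61, adjusted p = 3.8e-05), Tyrobp (4.79, SE 0.73, adjusted p = 2.5e-04), Mpeg1 (4.48, SE 0.50, adjusted p = 1.2e-05), Ms4a7 (4.41, SE 0.93, adjusted p = 0.00332) and C1qb (4.34, SE 0.65, adjusted p = 2.1e-04). Their direction too is between labels that Rxrg went against.

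Myelin and mature oligodendrocyte genes had a median of -1.49 and 0 of 27 members higher, 19 lower and 8 not called (camera adjusted p = 6.6e-19). Myelin members adjusted over the list alone came to 2 higher and 23 lower, and the list had adjusted p = 0.00437 with an estimated correlation. Mbp was at 627 ± 276 against 9596 ± 1339 CPM, and Mag and Hapln2 had log2 fold changes of -3.19 (SE 0.24) and -4.78 (SE 0.28). Committed and premyelinating genes had 1 of 17 members higher, 5 lower and 11 not called (camera adjusted p = 0.0178). Premyelinating members adjusted over the list alone came to 1 higher and 7 lower, and the list had adjusted p = 0.71 with an estimated correlation. Premyelinating examples were Rras2 (-1.41, SE 0.20) and the deacetylase Sirt2 (-1.04, SE 0.28). Cell cycle genes had 0 of 30 members higher, 13 lower and 17 not called (camera adjusted p = 1.4e-08). Cell cycle members adjusted over the list alone came to 0 higher and 15 lower, and the list had adjusted p = 0.382 with an estimated correlation. Cell cycle examples were Plk1 (-1.29, SE 0.21), Ube2c (-1.28, SE 0.20), Cdc20 (-1.19, SE 0.19) and Cenpf (-1.02, SE 0.15). The mean log2 CPM of the cell cycle list was 4.31 and 4.32 in the RXRgKO-labelled libraries with Xist, 5.08 and 5.14 in those lacking it and 5.22 to 5.62 in the WT-labelled ones, so most of the fall lay in 1 library set. Without the libraries with Xist its median was -0.21 (adjusted p = 0.0276). Cholesterol genes had 0 of 25 members higher, 2 lower and 23 not called (camera adjusted p = 0.0178). Cholesterol members adjusted over the list alone came to 0 higher and 2 lower, and the list had adjusted p = 0.71 with an estimated correlation. Cholesterol examples were Hsd17b7 (-1.63, SE 0.13) and Ebp (-0.98, SE 0.12). Circadian clock genes had 1 of 16 members higher, 6 lower and 9 not called (camera adjusted p = 0.00377). Circadian members adjusted over the list alone came to 1 higher and 6 lower, and the list had adjusted p = 0.382 with an estimated correlation. Circadian examples were Bhlhe41 (-2.07, SE 0.18) and Ciart (-1.19, SE 0.19). Mitochondrially encoded genes had 0 of 7 members higher, 1 lower and 6 not called (camera adjusted p = 0.00278). Mitochondrial members adjusted over the list alone came to 0 higher and 4 lower, and the list had adjusted p = 0.395 with an estimated correlation. Without WT-labelled replicate 1, the premyelinating, cholesterol and circadian lists were not called (adjusted p = 0.311, 0.163 and 0.0733), with medians of -0.31, 0.04 and -0.21. The cholesterol list was not called without RXRgKO-labelled replicate 3 or 4 either (0.0963 to 0.12). Without the RXRgKO-labelled libraries with Xist, the cholesterol and mitochondrial lists were not called (0.798 and 0.0697), and without those lacking Xist the premyelinating list was not (0.17).

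Neuron markers had 9 of 18 members higher, 1 lower and 8 not called (camera adjusted p = 4.1e-06). Neuron marker members adjusted over the list alone came to 14 higher and 1 lower, and the list had adjusted p = 0.282 with an estimated correlation. Neuron marker examples were Gad2 (2.44, SE 0.35), Dlx1 (1.82, SE 0.26), Gad1 (1.76, SE 0.30) and Dlx2 (1.56, SE 0.25). Microglia and macrophage markers had 12 of 13 members higher, 0 lower and 1 not called (camera adjusted p = 7.4e-10). Microglia members adjusted over the list alone came to 12 higher and 0 lower, and the list had adjusted p = 0.127 with an estimated correlation. The mean log2 CPM of microglia and macrophage markers was -0.26 and 0.20 in the RXRgKO-labelled libraries with Xist, 1.34 and 1.71 in those lacking it and -1.99 to -1.36 in the WT-labelled ones. Mesenchymal and mural markers had 11 of 13 members higher, 0 lower and 2 not called (camera adjusted p = 8.5e-09). Mesenchymal members adjusted over the list alone came to 11 higher and 0 lower, and the list had adjusted p = 0.0018 with an estimated correlation. Mesenchymal examples were Col3a1 (3.31, SE 0.47), Acta2 (3.09, SE 0.45) and Col1a1 (2.56, SE 0.29). Endothelial markers had 3 of 7 members higher, 0 lower and 4 not called (camera adjusted p = 6.0e-04). Endothelial members adjusted over the list alone came to 5 higher and 0 lower, and the list had adjusted p = 0.0334 with an estimated correlation. Endothelial examples were Cdh5 (3.04, SE 0.55) and Kdr (1.59, SE 0.30). Ependymal and ciliated markers had 6 of 7 members higher, 0 lower and 1 not called (camera adjusted p = 2.2e-06). Ependymal members adjusted over the list alone came to 6 higher and 0 lower, and the list had adjusted p = 0.127 with an estimated correlation. Ependymal examples were Cfap126 (2.39, SE 0.31) and Foxj1 (1.27, SE 0.18). The mean log2 CPM of the ependymal list was 1.44 and 1.53 in the RXRgKO-labelled libraries with Xist, 2.64 and 2.67 in those lacking it and 0.07 to 0.46 in the WT-labelled ones. Interferon response genes had 6 of 15 members higher, 0 lower and 9 not called (camera adjusted p = 5.9e-04). Interferon members adjusted over the list alone came to 9 higher and 0 lower, and the list had adjusted p = 0.316 with an estimated correlation. Interferon examples were Usp18 (2.23, SE 0.39) and Ifitm3 (1.84, SE 0.35). That of the interferon list was 1.01 and 1.0497 in the RXRgKO-labelled libraries with Xist, 2.04 and 2.04 in those lacking it and 0.53 to 0.80 in the WT-labelled ones. Retinoic acid target genes had 5 of 10 members higher, 1 lower and 4 not called (camera adjusted p = 0.0352). Retinoic acid members adjusted over the list alone came to 5 higher and 1 lower, and the list had adjusted p = 0.127 with an estimated correlation. The retinoic acid synthase Aldh1a2 (3.45, SE 0.67) and the degrading enzyme Cyp26b1 (1.72, SE 0.21) were higher, and the receptor Rarb (-1.98, SE 0.45) was lower. The retinoic acid list was not called without WT-labelled replicate 1 or RXRgKO-labelled replicate 3 (adjusted p = 0.0563 to 0.0984) or without the RXRgKO-labelled libraries with Xist (0.133), and the interferon list was not without those lacking Xist (0.0977). Of the T3 handling genes, Crym (3.20, SE 0.32) and Dio3 (1.81, SE 0.32) were higher and Dio2 (-1.29, SE 0.21) lower.

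The test called 2943 genes, 1600 higher and 1343 lower, 1695 of them by at least 2-fold. Reads outside annotated genes made up 14.9% ± 3.41 against 13.5% ± 0.940 (SD, n = 4; exact permutation test, two-sided, p = 0.429, 0.686 after adjustment). The count was 5955 (2550 higher and 3405 lower) without the RXRgKO-labelled libraries with Xist and 110 (41 higher and 69 lower) with counts summed per set, so the larger direction turned in both. The set term, which cannot adjust this comparison either, gave 9303.

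Of the genes called between labels, 877 were higher and 739 lower both without and with T3, where independent lists would share 98.8 and 69.3, and 1 changed in opposite directions. Mobp, Casr and S1pr5 are among the shared falls and C1qc, Lyz2, Fcrls and Ms4a7 among the shared rises. Across the 19764 genes, which are not independent replicates, Pearson's r was 0.8003 and Spearman's rho 0.728. The overlap was 3500 without the RXRgKO-labelled libraries with Xist and 66 with counts summed per set. With the set term, which takes the spread between sets out of the error and adjusts neither comparison, it was 6515.

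The labels give a mixed C57BL6J and 129 background, so calls were counted among the 50 nearest tested protein-coding genes on each side of Rxrg. Without T3, 16 of these 100 genes were called against 12.5% of the other genes (odds ratio 1.33, Fisher's exact test, two-sided, p = 0.289), and with T3 19 of 100 against 16.1% (odds ratio 1.23, p = 0.413). The collagen receptor Ddr2 (3.15, SE 0.17), Pcp4l1 (2.35, SE 0.29), Fmo1 (1.79, SE 0.25) and Cfap126 were higher and the protease Adamts4 (-4.09, SE 0.34) and Mpzl1 (-1.48, SE 0.20) lower without T3. With T3, Ddr2 (3.10, SE 0.17), Fmo1 (1.90, SE 0.26), Ankrd45 (1.03, SE 0.15) and Cfap126 were higher and Adamts4 (-3.43, SE 0.33) and Hsd17b7 lower. With counts summed per set, the odds ratio was 4.05 (p = 0.0421) without and 5.62 (p = 0.0188) with T3, by the same exact test.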

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

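In this part, the amplitude tests with library sets or with reads outside genes were chosen only after the result was seen.

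In groups of 4, a library was marked when its gap to the nearest other library, divided by the group's range, was above Dixon's 95% critical value of 0.829. Of 668 groups tested, 88 were above it; chance gives about 1 in 20. Of the 88, 78 were WT-labelled replicate 1, which stood apart from replicates 2 to 4 across the transcriptome, so these values are not independent of each other. Each value below is that gap over the range.

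Untreated WT-labelled replicate 1 was highest for total gene counts (0.853) and the mitochondrial share (0.866). Untreated WT-labelled replicate 1 was lowest for the share of reads placed at several sites (0.898). T3-treated WT-labelled replicate 1 was lowest for the share of reads placed at several sites (0.862).

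Of the mean log2 CPM of gene lists, these stood apart. T3-treated WT-labelled replicate 1 was highest for T3 transport, deiodination and receptors (0.950), OPC markers (0.962), committed and premyelinating oligodendrocyte genes (0.909), cell cycle (0.905), LXR target genes (0.900), astrocyte markers (0.888) and immediate early genes (0.853). Untreated WT-labelled replicate 1 was highest for OPC markers (0.896), committed and premyelinating oligodendrocyte genes (0.978), cholesterol synthesis and uptake (0.967), circadian clock genes (0.855), astrocyte markers (0.920), hypoxia and glycolysis genes (0.874) and sex-linked genes (0.9896). Untreated WT-labelled replicate 1 was lowest for neuron markers (0.928) and microglia and macrophage markers (0.840).

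Of named genes, in CPM, these stood apart. T3-treated WT-labelled replicate 1 was highest for Clca3a1 (0.845), Gbp3 (0.880), Stat5a (0.848), Opalin (0.881), Mog (0.925), Id4 (0.975), Fos (0.985), Tnc (0.903), Kif19a (0.883), Grin3a (0.844), Klf9 (0.853), Tmem163 (0.970), Cnksr3 (0.841), Sema3d (0.897), Foxj1 (0.865), Plk1 (0.925), Col3a1 (0.893) and Gfap (0.957). Untreated WT-labelled replicate 1 was highest for Col20a1 (0.938), Hr (0.918), Mog (0.845), Id4 (0.845), Junb (0.900), Kif19a (0.968), Rras2 (0.890), Klf9 (0.864), Cldn11 (0.865), Ugt8a (0.833), Tmem163 (0.927), Cnksr3 (0.936), Mbp (0.875), Ddc (0.840), Cdc20 (0.933), Adamts4 (0.962), Mpzl1 (0.911), Sirt2 (0.943), Fam135b (0.910), Gfap (0.954) and Ddx3y (0.968). T3-treated WT-labelled replicate 1 was lowest for Dio3 (0.912), Hapln2 (0.851), Hsd17b7 (0.923), Ebp (0.843), Mobp (0.952), Tmem125 (0.831), Mbp (0.923), S1pr5 (0.882), Adamts4 (0.852), Ermn (0.833) and Rarb (0.854). Untreated RXRgKO-labelled replicate 1 was lowest for Egfr (0.878). Untreated WT-labelled replicate 1 was lowest for Dlx1 (0.931), Gad1 (0.878), Gad2 (0.927), Nefl (0.921), Mobp (0.963), Tmem125 (0.928), Fmo1 (0.891) and Ermn (0.848). T3-treated WT-labelled replicate 2 was highest for Irx1 (0.865). Untreated WT-labelled replicate 3 was highest for Fcrls (0.829). Untreated WT-labelled replicate 4 was lowest for Lyz2 (0.920). Untreated RXRgKO-labelled replicate 3 was highest for Tmem125 (0.846). T3-treated RXRgKO-labelled replicate 2 was highest for Tmem125 (0.884). T3-treated WT-labelled replicate 4 was highest for Pifo (0.837) and Crym (0.837). Untreated WT-labelled replicate 2 was highest for Ciart (0.858). T3-treated RXRgKO-labelled replicate 2 was lowest for Rarb (0.893).

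With each library a replicate, the T3 response differed between genotype labels, by the test of the difference itself, for Edil3 (1.11), Thbs2 (-1.59), Fam135b (1.86), Hsd17b7 (-1.27), Pcolce (-2.04), Prr5l (-1.13), Ctsc (-1.24), Slc20a2 (-1.08) and Arhgap28 (-1.75), on the log2 scale. With counts summed per set, 0 genes passed this test, and leaving out 1 library at a time gave 3 to 49. By camera with the preset correlation the T3 response differed for the lists of cell cycle (median -0.33), cholesterol (-0.30), neuron (0.56), mesenchymal and mural (-0.58) and matrix and axon guidance genes (0.46). With an estimated correlation, and by fry, 0 of these 5 passed, 1 list having an unadjusted p under 0.05 with each. Of 100 splits of the libraries, 78 called as many lists. These splits shuffled genotype labels within each treatment, so they mix in the difference between labels and cannot decide on chance.

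The T3 response was smaller in the RXRgKO-labelled libraries over the genes changed by T3, with a median signed difference of -0.155. It was 0.0182 without the RXRgKO-labelled libraries lacking Xist and -0.257 without those with Xist, so its size depended on which library set was kept, and sets that differ in Xist stay open as its cause. With the share of reads outside genes as a covariate it was 0.161, but in the WT-labelled libraries that share does not overlap between treatments, so it cannot be told apart from T3 there. Chance was not excluded: 17 of 100 splits gave a difference as large, the highest other being 0.238. These splits too mix in the difference between genotype labels, so they cannot decide on chance. A difference between genotypes stays open and was not tested apart from these.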

How the results depend on the processing

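In this part, the library set as a term, summed counts, the covariate, the omission of whole library sets and the block on WT-labelled libraries alone were tests chosen only after the results were seen.

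Counts of called genes below are for T3 under the WT label, T3 under the RXRgKO label, the genotype labels without and with T3, and the response difference, where they moved by more than 1.5 times; the cause was not tested. With the library set as a term, which cannot adjust a comparison between genotype labels because each set holds 1 label and only takes the spread between sets out of the error, they were 7599, 6634, 8938, 9303 and 1321. With counts summed per library set, which leaves fewer libraries, they were 15, 3, 141, 110 and 0 by edgeR, the last with 159 genes at an unadjusted p under 0.05; with each library a replicate, edgeR gave 13 and DESeq2 112. With the share of reads outside genes as a covariate, both T3 counts were 4744 and 4989 and the difference 81. Without the 2 WT-labelled libraries numbered 1 these 3 were 2688, 1540 and 118. Without the RXRgKO-labelled libraries lacking Xist, T3 under the WT label gave 2800 and the difference 26. Without those with Xist, the 4 pairwise counts were 2626, 129, 4518 and 5955. The replicate block gave 5084 for T3 in the WT-labelled libraries alone and 4 for the difference in all. DESeq2 gave 1194 for T3 under the RXRgKO label, and the filter of 1 CPM in 4 libraries gave 20 for the difference.

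The amplitude was -0.0589 with the set as a term, -0.429 with summed counts, 0.161 with the covariate and 0.0182 without the RXRgKO-labelled libraries lacking Xist; the last pair reversed its direction, and the cause was not tested. With the set as a term and with summed counts it no longer passed. It was -0.257 without those with Xist and -0.238 without a low-count filter. The overlap of T3 calls was 4117 with the set as a term, 2 summed, 3134 with the covariate, 911 without WT-labelled replicate 1 and 121 without the RXRgKO-labelled libraries with Xist. The overlap between genotype comparisons was 6515 with the set as a term, 66 summed and 3500 without those with Xist. Odds ratios near Rxrg were 4.05 and 5.62 with summed counts.

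Lists called were 7, 9, 11, 13 and 5 by camera with the preset correlation. With an estimated correlation they were 2, 2, 3, 3 and 0; fry gave 3 for T3 under the RXRgKO label and 0 for the difference, and for both counts of 0 an unadjusted p under 0.05 was reached by 1 list. Fry in either direction gave 19, 15, 20, 23 and 1, and summed counts gave 3 and the omission of the RXRgKO-labelled libraries lacking Xist 8 for the difference.

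Leaving out 1 library at a time gave counts of 997 to 2475, 253 to 500, 1712 to 2206, 2178 to 3195 and 3 to 49, an amplitude of -0.228 to -0.1005, overlaps of 200 to 545 and 1318 to 1671, and list counts of 7 to 9, 8 to 9, 8 to 12, 10 to 13 and 4 to 8. Of these, T3 under the WT label gave 997, 998 and 1009 without untreated WT-labelled replicate 2, 3 or 4 and 1065 without T3-treated replicate 4.

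Of 4624 comparisons of the 205 named gene results with their alternatives, 4251 kept direction and side of the threshold, 357 were no longer past it, 15 passed it newly and 1 reversed. That was Xist between genotype labels without T3, at 1.80 with the covariate; the cause was not tested. With counts summed per set, 148 of 205 were no longer past the threshold, and 52 results changed under none of the alternatives run. DESeq2 size factors shifted the median of all genes by at most 0.0246 on the log2 scale.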

Other observations

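In this part, the tests of exchanged labels, of a disrupted allele and of a lower oligodendrocyte share, and those with the covariate, with library sets left out or as a term and with summed counts, were chosen only after the results were seen. Counts of splits were not.

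Gene lists not described so far were called in none of the 5 comparisons by camera with the preset correlation, and for each called list the median, the mean and the test had the same sign. Between genotype labels with T3, the log2 medians and members called were: T3 transport, deiodination and receptors 0.20 (4 higher, 3 lower of 13; adjusted p = 0.33), nuclear receptor partners of RXR and coregulators -0.02 (2 higher, 2 lower of 16; adjusted p = 0.985), LXR target genes 0.16 (2 higher, 0 lower of 12; adjusted p = 0.24), PPAR target genes 0.09 (3 higher, 1 lower of 15; adjusted p = 0.824), neural stem cell and radial glia markers 0.22 (2 higher, 0 lower of 14; adjusted p = 0.177), astrocyte markers -0.07 (0 higher, 0 lower of 14; adjusted p = 0.985), Schwann and neural crest markers -0.09 (1 higher, 1 lower of 7; adjusted p = 0.985), ATF4 and amino acid stress genes 0.17 (0 higher, 2 lower of 16; adjusted p = 0.327). For T3 under the WT label they were: T3 transport, deiodination and receptors -0.12 (1 higher, 2 lower of 13; adjusted p = 0.914), nuclear receptor partners of RXR and coregulators -0.11 (0 higher, 1 lower of 16; adjusted p = 0.86), LXR target genes 0.18 (1 higher, 1 lower of 12; adjusted p = 0.617), PPAR target genes 0.04 (2 higher, 4 lower of 15; adjusted p = 0.61), neural stem cell and radial glia markers 0.04 (1 higher, 0 lower of 14; adjusted p = 0.393), astrocyte markers 0.19 (1 higher, 0 lower of 14; adjusted p = 0.244), Schwann and neural crest markers -0.01 (1 higher, 0 lower of 7; adjusted p = 0.61), ATF4 and amino acid stress genes 0.09 (1 higher, 0 lower of 16; adjusted p = 0.392).

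Rxrg was higher in the RXRgKO-labelled libraries. Reads outside annotated genes are argued against as the cause, since with their share as a covariate the log2 fold change with T3 was 2.75. Genotype labels exchanged between the groups stay open: the lowest RXRgKO-labelled library had 2.11 times the Rxrg of the highest WT-labelled one, which restates the pattern and gives no support. Reads of a disrupted allele counted to the gene stay open too, since 8 of 8 RXRgKO-labelled libraries had over 3 counts, as an intact gene would give. The disrupted part of the gene is not given in the sources used here, so neither is excluded.

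Myelin genes were lower in the RXRgKO-labelled libraries. Reads outside genes are argued against, since with the covariate the list's median nearest to 0 over both comparisons was -1.49. A fall carried by only 1 of the RXRgKO-labelled sets that differ in Xist is argued against, since with either set left out that median was -1.55. Each set holds a single genotype label, so this cannot separate a difference between sets or cultures from the label. A lower oligodendrocyte share that raised every other cell type alike is argued against, since medians of 8 other cell type lists differed by 3.09, from astrocyte markers to mesenchymal and mural markers. A change in particular cell types and a difference between genotypes may account for the pattern, under labels that Rxrg went against.

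Other splits of the libraries were counted for each result, with the libraries taken as exchangeable. The library sets go against that, so a small share of splits below does not exclude chance. For genes changed by T3 under the WT label, 1 of 35 splits was as large (real 1668, highest other 101), counted over splits that ignore the replicate numbers. Taken as pairs, the numbers leave 8 splits that part all 4, too few for a share under 0.05, with a highest other of 0. The 27 others part fewer. These splits cannot separate T3 from the difference in Xist and Ddx3y between treatments in WT-labelled replicates 2 to 4. Between genotype labels, 1 of 35 splits was as large without T3 (2240, highest other 0) and 1 of 35 with T3 (2943, highest other 0). No other split of 4 against 4 keeps these library sets whole, so these counts cannot decide on chance, which stays open at the level of sets. By this count chance could not be excluded for T3 under the RXRgKO label (555, 2 of 35). The other split as large follows the library sets, untreated replicates 1 and 3 with T3-treated 1 and 2. It gave 7865 genes, which points to a structure of the samples and not to an arbitrary split. With the set as a term the T3 count was 6634, and with counts summed per set it was 3. The set term leaves only the spread within sets as error, and these sets are not shown to be the same cultures in both treatments. The count of 6634 therefore gives no ground to exclude chance. For the response difference, 5 of 100 splits were as large (13, highest other 418). These splits shuffled genotype labels within each treatment, so they mix in the difference between labels. They cannot decide on chance and do not exclude it. For lists called between genotype labels with T3, 1 of 35 splits was as large (13, highest other 12). That margin is narrow: leaving out 1 library gave 10 to 13 lists, and an estimated correlation gave 3, so chance is not excluded. Nor could it be for lists called for T3 under the WT label (7, 17 of 35, highest other 13) or the RXRgKO label (9, 4 of 35, highest other 9). The same holds between labels without T3 (11, 12 of 35, highest other 13). For the lists of the response difference, 78 of 100 splits were as large (5, highest other 14), with the same limit as for its genes.

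Whole library sets, 2 in each group, allow 3 splits per pairwise comparison, too few for a share under 0.05, so these counts of splits do not reach to the level of sets, for genes or for lists. With counts summed per set, edgeR called 15 genes for T3 under the WT label, 3 under the RXRgKO label, and 141 and 110 between genotype labels without and with T3.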
